A study of Homo sapiens with 6 samples.

How the data were processed

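Polyadenylated RNA of HL60 cells was sequenced from 6 libraries made with a stranded mRNA kit, per the labels' protocols. The submitters' processing notes name bcl2fastq, TopHat2, Subread with featureCounts, DESeq and DESeq2, and the genome build hg19 (GRCh37). Versions, the gene annotation, the strand setting and the treatment of reads shared by several genes are not given in the sources used here. The authors deposited raw counts per gene with the gene length, and these counts were the input of every test. Library totals were between 47930276 and 58553247 counts, and 3 counts in knockout replicate 3, for example, corresponded to 0.0572 CPM. A second deposited table holds counts divided by size factors, a signal on the scale of reads, for 21935 genes with at least 10 reads over the 6 libraries. Checked against the raw counts, each of its 3357 zero counts had been set to 1 before division, and no other value differed from the count over its size factor by more than 0.001 read. That table also holds the authors' log2 fold changes with standard errors, a test score and p-values, in which 2613 genes had an adjusted p under 0.05, 1464 of them higher. Of the 1932 genes called here, 1904 passed in the authors' deposited table too, with the same sign.

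Libraries were assigned to 3 SKI knockout and 3 control replicates from the titles, and count columns were matched to them by group and replicate number. The comparison was fixed before the data were examined as knockout against control with group as the only term, together with the gene lists and the rule for naming genes. Genes were kept by edgeR's filterByExpr, scaled by TMM and tested with the quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjusted p-values and a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2.

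The 33 gene lists cover lineages, pathways and SKI partners. The 31 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Members past the threshold were counted with p-values adjusted over all genes tested and over the list alone. These counts are out of the tested members, and members removed by the filter are left out. Adjusted p-values given in parentheses after list counts are those of camera at the preset correlation. The text names SKI and SKIL, and genes with an average log2 CPM of at least 2, an adjusted p under 0.05 and groups that do not overlap. Of these it names the 8 largest increases and decreases, and the 4 largest differences of mean CPM in each direction. From each list up to 4 members past the threshold with the smallest p may be named, 115 genes in all. Exons of 30 of these overlap a gene on the opposite strand and those of 12 a gene on the same strand. Overlaps, chromosome membership, gene order and transcript GC content were taken from GENCODE release 29 by gene symbol, which is on a later build than the counts, so no coordinates are given. A chromosome was found for 84.7% of tested genes. Chromosome medians use genes with an average log2 CPM above 2, and their camera test all tested genes.

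Alternatives were DESeq2's size factors, library totals, the authors' size factors, no filter, a filter of CPM at least 1 in 3 libraries, DESeq2's Wald test (DESeq2 1.42.0), limma-voom, the replicate number as a block, and leaving out each library. Alternatives chosen after the data were examined centred each gene on its chromosome or on its 50 nearest neighbours, removed the trend of each library with GC content or gene length (lowess span 0.3), or left out 2 libraries at once. The scripts were tested on simulated data, with counts drawn for 16340 genes from the fitted means and dispersions of this comparison. The 200 changed genes were drawn only from those with an average log2 CPM above 2. Of their changes, 78% of 2-fold and 100% of 4-fold ones were recovered, and 6.81% of calls were unchanged genes. With a simulated shift of -0.5 for chromosome 19, 70 unchanged genes of that chromosome were called before chromosome centring and 0 after it.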

Results

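RNA sequencing was used to compare HL60 cells in which the gene SKI had been targeted by CRISPR/Cas9 with HL60 cells carrying a CRISPR/Cas9 control. HL60 is a human acute myeloid leukaemia line of promyelocytic character, and SKI encodes a co-repressor that binds SMAD proteins and other transcription factors. There were 6 libraries, 3 from the knockout and 3 from the control, and cells were grown in 10% serum. The knockout libraries came from the line numbered 3 and the control libraries from the line numbered 1, so each group held 1 line. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Library totals ran from 47930276 to 58553247 counts over 56638 gene names, and 16340 genes were tested. Between 23295 and 25003 genes had at least 1 count in a library. Libraries of a group correlated across genes, which are not independent replicates, with a Spearman coefficient of at least 0.991 in the control and 0.979 in the knockout. No pair within a group was alike within counting noise, since 68.9% to 85.5% of well-counted genes differed by more than that noise in every pair.

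SKI mRNA was lower in the knockout but far from absent, and its relative SKIL was higher. SKI stood at 63.9, 83.5 and 88.5 CPM in the control libraries and at 59.6, 40.7 and 42.0 CPM in the knockout libraries. The means were 78.7 ± 13.0 CPM (SD, n = 3) and 47.4 ± 10.5 CPM (SD, n = 3), a log2 fold change of -0.73 (SE 0.19) with an edgeR adjusted p of 0.0282. All 3 knockout values lay below all 3 control values. Editing of coding sequence need not lower an mRNA, so this level neither proves nor disproves loss of the protein. The call was lost without control replicate 2 (log2 -0.69, adjusted p = 0.109), control replicate 3 (-0.64, 0.136) or knockout replicate 2 (-0.61, 0.0769). Those fits kept the direction and held fewer libraries, so the lost calls need not mean that SKI depended on 1 library. The call also ended with library totals (log2 -0.69, adjusted p = 0.0673). Among alternatives chosen after the data were examined, it ended with neighbour centring (-0.46, 0.164) and GC trends removed (-0.62, 0.0578). The authors' deposited table gives SKI a log2 fold change of -0.66 with an adjusted p of 0.0125. SKIL, a SKI-family gene that is itself a target of TGF-beta signalling, went from 3.56 ± 0.874 to 11.8 ± 2.92 CPM (SD, n = 3), a log2 fold change of 1.72 (SE 0.26, adjusted p = 0.00193).

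**Figure D1:**
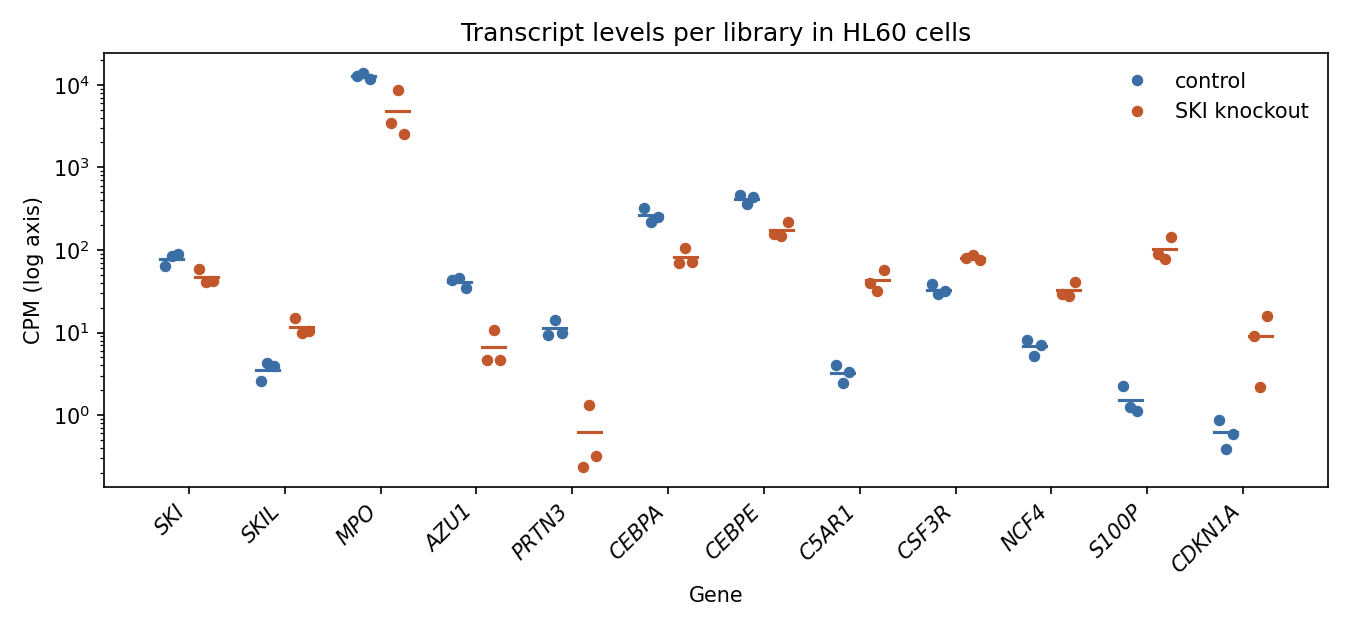
CPM on a log axis for 12 genes in each of the 3 control and 3 SKI knockout libraries, with points for libraries and short lines for group means. SKI lay between 63.9 and 88.5 CPM in the control and between 40.7 and 59.6 CPM in the knockout. The groups did not overlap for any of the genes drawn, which the naming rule required of those chosen for the largest changes.

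The comparison of knockout with control asks how the transcriptome of HL60 cells differs where SKI was targeted. Of 30 genes of mature neutrophils 20 were tested, of which 12 rose in the knockout, 1 fell and 7 did not pass. Their median log2 fold change was 1.06 (camera adjusted p = 7.18e-12, and adjusted p = 0.395 with an estimated correlation). Among them, the complement receptor gene C5AR1 was 13.3-fold higher. The granule protease gene PRTN3 was 18.1-fold lower, and CEBPA and CEBPE, transcription factors of granulocyte development, were 3.19-fold and 2.41-fold lower. Each gene was also centred on its neighbours, an alternative chosen after the data were examined. The log2 fold changes of PRTN3, CEBPA and CEBPE were then smaller, at -3.48, -1.26 and -0.89, and that of C5AR1 larger, at 4.18. All of them kept their calls. In edgeR's quasi-likelihood test 1932 of 16340 genes passed an adjusted p of 0.05, 1012 higher and 920 lower in the knockout. A change of at least 2-fold was seen in 626 of the higher and 384 of the lower genes. Values of the groups did not overlap for 32.2% of tested genes, where chance gives 10%. The count was 932 without control replicate 2, 740 without control replicate 3 and 1025 without knockout replicate 1, and 605 genes were lower without control replicate 1. With each gene centred on the median of its chromosome, an alternative chosen after the data were examined, 845 genes were higher and 506 lower, so that 62.5% of calls were higher in place of 52.4%.

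The 8 largest increases among named genes were in KRT81, GDF15, S100P, NFKBIZ, PCDH12, EMID1, CDKN1A and C5AR1. S100P, a calcium-binding protein of the S100 family, rose 67.7-fold, from 1.54 ± 0.642 to 104 ± 35.7 CPM (SD, n = 3, log2 SE 0.34, adjusted p = 6.93e-06). C5AR1, the receptor for complement fragment C5a on neutrophils, rose 13.3-fold, from 3.28 ± 0.781 to 43.4 ± 13.0 CPM (SD, n = 3, adjusted p = 2.69e-05). PCDH12, a protocadherin, rose 18.5-fold with an adjusted p of 1.46e-05. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 14.6-fold, and its knockout libraries were spread from 2.17 to 15.8 CPM. GDF15, a stress-induced cytokine, was below 0.231 CPM in every control library and at 7.70, 0.476 and 17.5 CPM in the knockout libraries. NFKBIZ, an inducible regulator of NF-kappaB targets, rose 22.8-fold and EMID1 17.4-fold. KRT81, a hair keratin, had a log2 fold change of 6.44, close to that of its near-identical neighbour KRT86 at 6.38, a gene looked up after its values were seen, and reads shared between them leave both values uncertain. Single libraries moved 4 of these estimates by more than 1.5-fold: without knockout replicate 3 the log2 fold change was 5.53 for KRT81, 5.20 for GDF15 and 3.21 for CDKN1A, and without knockout replicate 1 it was 3.70 for NFKBIZ. That of GDF15 was 7.09 without control replicate 1, and limma-voom did not call this gene (adjusted p = 0.0605).

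The 8 largest decreases were in NCALD, ZNF704, CACHD1, IGFBP2, ZNF551, PRTN3, PTCH1 and ZNF618. NCALD, a neuronal calcium sensor, fell from 23.0 ± 2.65 to 0.425 ± 0.139 CPM (SD, n = 3, adjusted p = 1.79e-06), 53.6-fold lower. ZNF704 was 43.9-fold lower and CACHD1 36.5-fold lower. IGFBP2, an insulin-like growth factor binding protein, was 28.1-fold lower, at 0.747 ± 0.529 CPM in the knockout (SD, n = 3). PTCH1, the Hedgehog receptor, was 13.4-fold lower. PRTN3, which encodes the granule protease proteinase 3, was 18.1-fold lower, at 0.628 ± 0.605 CPM in the knockout (SD, n = 3). With each gene centred on its neighbours, an alternative chosen after the data were examined, PRTN3, which lies on chromosome 19, was at -3.48 on the log2 scale, against -4.18. Decreases were larger without a single library for PRTN3 (-5.30 on the log2 scale without knockout replicate 2), PTCH1 (-4.38 without the same), IGFBP2 (-5.53 without knockout replicate 3) and ZNF551 (-5.41 without knockout replicate 1). Exons of NCALD and PTCH1 overlap genes on the opposite strand, and whether counting used the strand is not given in the sources used here.

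Measured by the difference in mean CPM, the largest decreases were in MPO, CALR, MYC and BZRAP1, and the largest increases in EIF3D, C6orf48, WARS and TRIB3. MPO, the myeloperoxidase of azurophil granules and the most abundant gene in control replicate 2, went from 12752 ± 1184 to 4857 ± 3220 CPM (SD, n = 3, log2 -1.39, adjusted p = 0.0365). Its call was lost without control replicate 1 (log2 -1.40, adjusted p = 0.0600), control replicate 2 (-1.32, 0.108), control replicate 3 (-1.46, 0.103) and knockout replicate 1 (-1.20, 0.135). The MPO log2 fold change had an adjusted p of 0.0667 in DESeq2, and was -2.06 without knockout replicate 2. MYC fell from 1320 ± 264 to 651 ± 264 CPM (SD, n = 3, log2 -1.02, adjusted p = 0.0376), and without those 4 libraries its adjusted p was 0.0865, 0.0501, 0.153 and 0.115. CALR, a chaperone of the endoplasmic reticulum, fell by 0.85 on the log2 scale, with an adjusted p of 0.0545, 0.0521, 0.0668 and 0.0507 without the same libraries. BZRAP1 fell from 687 ± 85.0 to 152 ± 93.6 CPM (SD, n = 3, adjusted p = 0.00338). EIF3D, a translation initiation factor subunit, rose by 0.66, C6orf48 by 0.97, WARS, a tryptophanyl-tRNA synthetase, by 0.89 and TRIB3, a target of the stress factor ATF4, by 0.69 on the log2 scale. Without control replicate 3 the adjusted p of these 4 genes was 0.108, 0.0577, 0.0559 and 0.0958. EIF3D and TRIB3 also lost their calls without control replicate 1 (0.0962 and 0.0726) and control replicate 2 (0.155 and 0.112), as did C6orf48 without control replicate 2 (0.0571). Chromosome centring ended the calls of EIF3D (log2 0.44, adjusted p = 0.143), C6orf48 (0.56, 0.103) and CALR (-0.37, 0.266). That of MYC narrowly missed (0.0539) with its log2 fold change at -0.98, little moved.

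Expression of whole chromosomes differed between the lines, a comparison chosen after the data were examined. Over 693 genes of chromosome 19 the median log2 fold change was -0.48, and 85.9% of them were lower in the knockout. The median of chromosome 19 genes against the control mean was -0.53, -0.55 and -0.38 in the knockout libraries, while control libraries lay between -0.03 and 0.03. Over 517 genes of chromosome 6 the median was 0.43, with 0.41, 0.43 and 0.44 in the knockout libraries. Chromosome 22 had a median of 0.23 and chromosome 9 one of -0.23, in which the lower genes lay in the latter part of the gene order. Chromosome 14, where CEBPE lies, had a median of -0.19, with medians from -0.48 to -0.30 in bins 1 to 5 of 10 along the gene order, and 26 genes higher and 52 lower. On chromosome 19 lay 280 of the 920 lower genes, and on chromosome 6 168 of the 1012 higher genes. In camera with the preset correlation, 4 of 23 chromosomes passed, namely 6, 9, 19 and 22. With an estimated correlation only chromosome 6 passed (adjusted p = 0.00177), and chromosomes 9, 14, 19 and 22 each had an adjusted p of 0.128. Without the calls placed on chromosomes 6, 19 and 22, 732 genes were higher and 627 lower, a tally that includes genes for which no chromosome was found, and chromosome 9 with 17 higher and 83 lower.

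**Figure D2:**
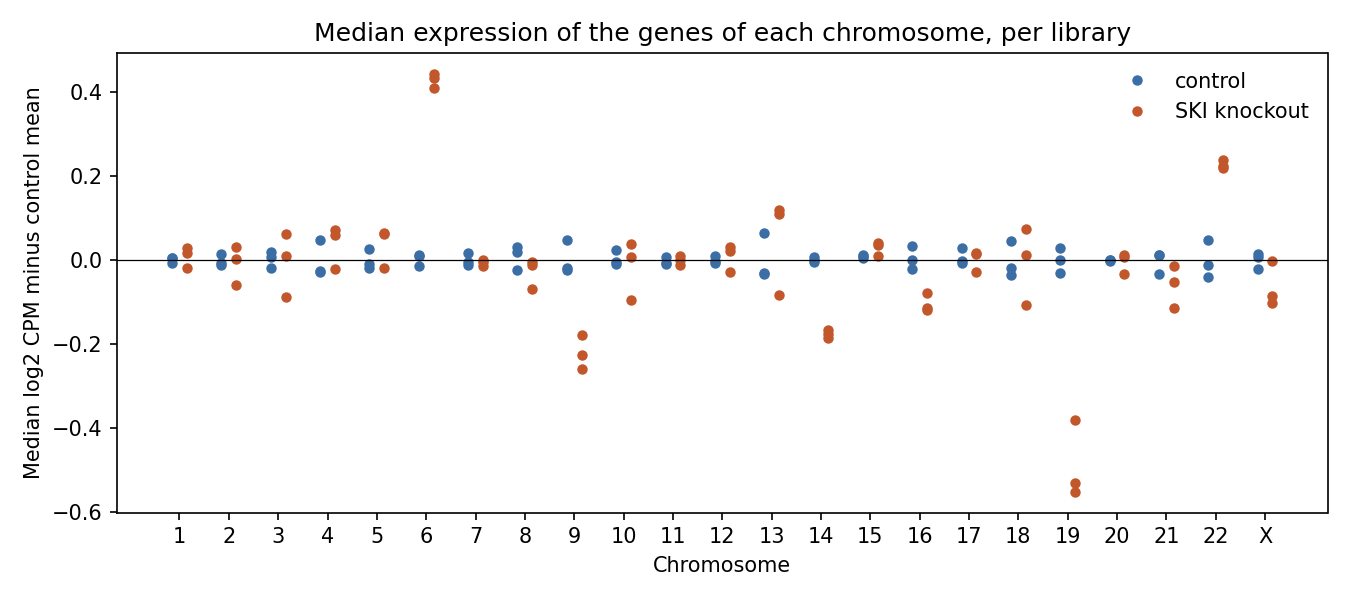
Median over genes of log2 CPM minus the control mean, for each chromosome (x axis) and each library, with control and SKI knockout libraries as points in 2 colours. Knockout libraries lay between -0.55 and -0.38 for chromosome 19 and between 0.41 and 0.44 for chromosome 6.

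Most of the mature neutrophil genes tested rose, whereas primary granule genes moved in both directions. The mature neutrophil list had 30 members, and only 20 had enough counts to be tested. Of these 20, 12 rose, 1 fell and 7 did not pass, with a median of 1.06, and adjusted over the list alone 13 rose and 2 fell. NCF4, a subunit of the NADPH oxidase, rose from 6.80 ± 1.47 to 32.4 ± 7.40 CPM (SD, n = 3), and CSF3R, the receptor for G-CSF, from 33.2 ± 4.71 to 80.4 ± 6.18 CPM (SD, n = 3, adjusted p = 0.000795). ITGAX, an integrin of myeloid cells, had a log2 fold change of 2.13 (adjusted p = 0.000788). S100A9, among the most abundant transcripts of mature neutrophils, rose from 0.0832 ± 0.0572 to only 0.466 ± 0.189 CPM (SD, n = 3, adjusted p = 0.0147). The list passed camera at an adjusted p of 7.18e-12, and had an adjusted p of 0.395 with an estimated correlation. Of 18 primary granule genes, 5 rose and 8 fell (5 and 9 adjusted over the list alone), with a median of -0.47. AZU1, a granule protein encoded beside PRTN3, went from 41.3 ± 5.97 to 6.68 ± 3.47 CPM (SD, n = 3, adjusted p = 0.000591), a log2 fold change of -2.63, or -1.93 with neighbour centring. SERPINB1, an inhibitor of granule proteases, rose by 1.48 on the log2 scale, or by 1.01 with neighbour centring. The primary granule list just passed at an adjusted p of 0.0482, and had an adjusted p of 0.683 with an estimated correlation. It passed in 8 of 21 alternatives, and no longer did without control replicate 1 (0.121), knockout replicate 1 (0.134) or knockout replicate 3 (0.0974), in DESeq2 (0.0903) or in limma-voom (0.169).

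Other blood lineage lists gave a mixed picture. Of 11 eosinophil and mast cell genes 6 rose and 1 fell, also adjusted over the list alone, with a median of 1.02 and a camera adjusted p of 0.00762 (adjusted p = 0.415 with an estimated correlation). SIGLEC8, a receptor of eosinophils, went from 0.0681 to 0.826 CPM (log2 3.56, or 4.17 with neighbour centring), and MS4A2, a chain of the high-affinity IgE receptor, from 0.311 to 0.0129 CPM, all low levels. Only 7 of 22 secondary granule genes were tested, of which 2 rose and 2 fell (2 and 3 adjusted over the list alone). The 7 had a median of -0.66, a mean of 0.03 and a lower direction in camera (adjusted p = 0.595). Among 18 monocyte and macrophage genes 3 rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.707), with CD68 up by 1.52 and CCR2 down at a log2 fold change of -2.73. Of 18 stem and progenitor genes 2 fell (2 higher and 3 lower adjusted over the list alone, 0.453). Only 9 of 30 erythroid and megakaryocyte genes were tested, of which 1 fell, KLF1, as it did adjusted over the list alone (0.453). Of 10 lymphoid genes 2 rose and 3 fell by either adjustment (0.453), with LCK at a log2 fold change of 3.12 and TRAC at -1.58. The non-blood list had 4 tested members, of which 1 rose (3 adjusted over the list alone), and the MHC class II list had 3, of which none passed by either adjustment, too few for the list test.

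Transcription factors and signalling genes of the myeloid programme changed in both directions. Of 32 myeloid transcription factor genes 6 rose and 6 fell (8 and 12 adjusted over the list alone). CEBPA fell from 264 ± 52.3 to 82.7 ± 20.4 CPM (SD, n = 3, log2 -1.67, adjusted p = 0.000823) and CEBPE from 418 ± 50.5 to 173 ± 38.8 CPM (SD, n = 3, adjusted p = 0.00194). With neighbour centring CEBPA was at -1.26 and CEBPE at -0.89 on the log2 scale. The median of that list was 0.01 and its mean 0.10, while camera gave a lower direction (adjusted p = 0.413). TAL1 had no read in any control library and 0.247 ± 0.0541 CPM in the knockout (SD, n = 3). Of 25 genes bound or regulated by RUNX1, 7 rose and 6 fell (8 and 10 adjusted over the list alone). Their median was 0.03 and mean 0.05 against a lower direction in camera (adjusted p = 0.834). Of 25 TGF-beta and BMP target genes 7 rose, among them NEDD9 and BHLHE40 at log2 fold changes of 1.30 and 1.40, and 4 fell (8 and 4 adjusted over the list alone). After chromosome centring NEDD9 was at 0.89 and BHLHE40 at 1.40, and 9 of the called members kept their call. The median of these 25 target genes was -0.04 and their mean 0.26 before centring, with a higher direction in camera (adjusted p = 0.453). Of 23 co-repressor partner genes 2 rose and 2 fell by either adjustment (0.595). Among 30 cytokine receptor and signalling genes 6 rose, including IL2RG at 1.12 and CSF2RB at 2.28, and 4 fell (8 and 4 adjusted over the list alone, 0.303). Of 27 adhesion and migration genes 8 rose and 4 fell (9 and 5 adjusted over the list alone, 0.235). Of 16 retinoic acid genes 3 rose, among them DHRS9 at 3.64 and RARRES3 at 2.48 (1.85 without knockout replicate 3), and 2 fell (3 and 4 adjusted over the list alone, 0.707). Of 20 Hedgehog and Wnt genes 2 rose and 2 fell, with SMO at -2.54 beside PTCH1 (the same by either adjustment, 0.164).

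In lists of stress, p53 target, apoptosis, NF-kappaB, interferon and MHC class I genes, some members rose and most did not pass the test. All 6 lists passed camera with the preset correlation and none with an estimated one. Of 24 genes of the ATF4 and unfolded protein responses 6 rose and 2 fell (10 and 2 adjusted over the list alone). CTH, an enzyme of cysteine synthesis, was at a log2 fold change of 1.06. The stress list had a camera adjusted p of 0.00302 (adjusted p = 0.415 with an estimated correlation). After chromosome centring 4 of its called members kept their call, though its median was 0.38 against 0.39 before. Of 22 p53 target genes 4 rose, namely CDKN1A, GDF15, GADD45A at 1.41 and FAS at 1.14 (6 higher and 1 lower adjusted over the list alone). The p53 target list had a camera adjusted p of 0.00302 (adjusted p = 0.415 with an estimated correlation). Of 29 apoptosis genes 3 rose, with TNFSF10, which encodes TRAIL, at 1.56 (5 higher and 1 lower adjusted over the list alone). The apoptosis list had a camera adjusted p of 0.0353 (adjusted p = 0.415 with an estimated correlation). It no longer passed without control replicate 1 (0.0691) or control replicate 3 (0.0556). After chromosome centring its adjusted p was 0.0503, though its median was 0.30 against 0.29 before. Of 22 NF-kappaB and inflammatory genes 4 rose by either adjustment, with the chemokine CCL5 going from 17.0 ± 7.80 to 115 ± 20.4 CPM (SD, n = 3), at a camera adjusted p of 0.00126 (adjusted p = 0.633 with an estimated correlation). Of 36 interferon-induced genes 6 rose, including IFI16 at 1.55 and IFITM3 at 1.38 (7 adjusted over the list alone), at a camera adjusted p of 0.0201 (adjusted p = 0.736 with an estimated correlation). That call was lost without control replicate 2 (0.0899) or knockout replicate 3 (0.416). Of 12 MHC class I genes 5 rose (7 adjusted over the list alone), at a camera adjusted p of 0.00126 (adjusted p = 0.633 with an estimated correlation). All 5 lie on chromosome 6, and with each gene centred on its chromosome only HLA-B kept its call (adjusted p = 0.0239) and the list had an adjusted p of 0.227. Reads shared among HLA genes leave their values uncertain.

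Some MYC-linked and cholesterol synthesis genes fell, while most members of these and of the cell cycle lists did not pass the test. Of 32 MYC target and ribosome biogenesis genes 5 fell (7 adjusted over the list alone), with a median of -0.38 and a camera adjusted p of 0.000194 (adjusted p = 0.683 with an estimated correlation). The rotation test fry gave that list an adjusted p of 0.166, and after chromosome centring 1 of the 5 kept its call, though the list still passed camera and its median was -0.37. PPAN, a ribosome assembly factor on chromosome 19, went from -0.98 to -0.49 with centring (adjusted p = 0.0906), while MYC, whose call was also lost without single libraries, missed the threshold (0.0539) with little change in fold, at -0.98. Of 25 cholesterol synthesis genes 6 fell (7 adjusted over the list alone), with LSS, lanosterol synthase, going from 91.6 ± 3.92 to 46.0 ± 4.24 CPM (SD, n = 3, adjusted p = 0.00173). The cholesterol list had a camera adjusted p of 0.0128 (adjusted p = 0.683 with an estimated correlation), one of 0.103 without knockout replicate 1, and one of 0.124 in fry. After chromosome centring 4 of its 6 called members kept their call. Of 34 G2/M genes 2 rose and none passed adjusted over the list alone (0.864), with a median of -0.03, a mean of 0.02 and a higher direction. Of 36 S phase genes 3 fell by either adjustment (0.235), all on chromosome 19, and after chromosome centring none kept its call. Of 20 cyclin and CDK inhibitor genes 4 rose, including CCND1 at 3.63, and 1 fell, by either adjustment (0.363). Among 26 hypoxia and glycolysis genes 3 rose, with the glucose transporter gene SLC2A3 at 1.94, and 2 fell (6 and 2 adjusted over the list alone, 0.834), at a median of -0.14, a mean of 0.11 and a higher direction. Of 20 immediate early genes 2 rose and 3 fell (4 and 4 adjusted over the list alone, 0.834), at a median of -0.08, a mean of 0.05 and a lower direction. Of 15 replication histone genes 2 rose and 1 fell by either adjustment (0.453). Both that rose lie on chromosome 6 and lost their calls after chromosome centring, where the list median went from 0.26 to -0.15. Of 13 mitochondrially encoded genes none passed by either adjustment (0.716). Of the 31 lists tested, 11 passed with the preset correlation and 0 with an estimated one, where 2 lists had an unadjusted p under 0.05, while the rotation test fry called 5, namely mature neutrophil, eosinophil and mast cell, p53 target, apoptosis and stress genes.

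**Figure D3:**
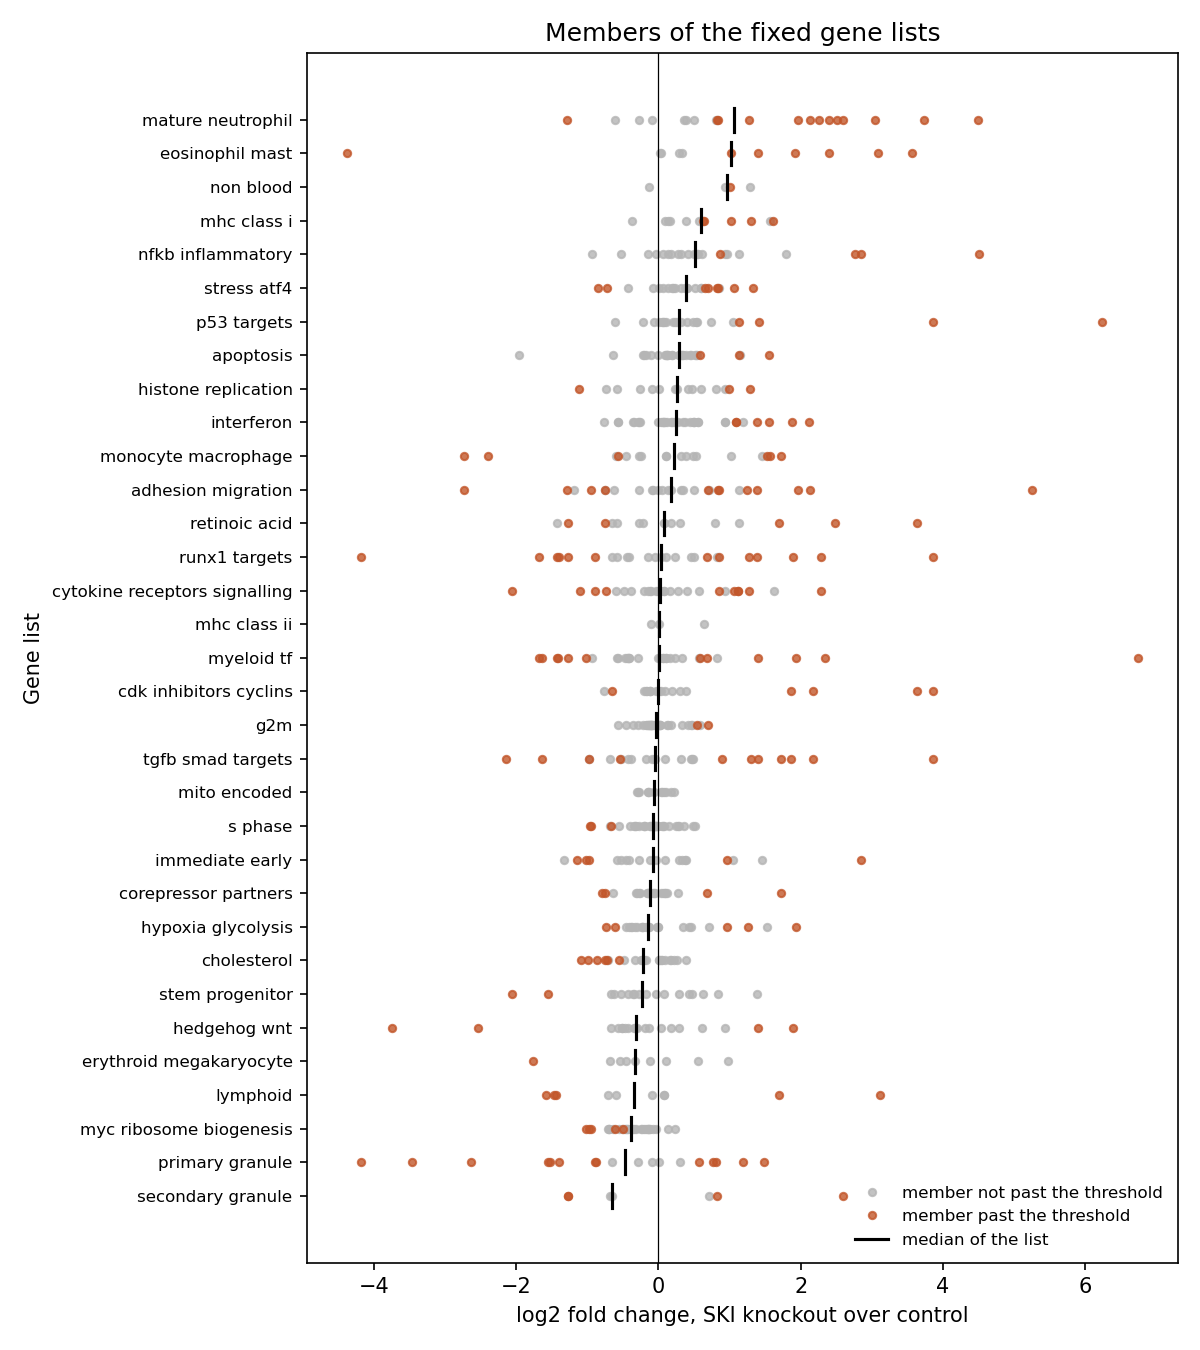
Log2 fold change of SKI knockout over control (x axis) for each tested member of the 33 fixed lists (y axis), with members past the threshold in orange, the others in grey and list medians as black bars. The mature neutrophil median was 1.06 and the primary granule median -0.47, and the point of TAL1, a gene with no control reads, depends on the prior count.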

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

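The tests with chromosome or neighbour centring, GC or length trends and with 2 libraries removed were chosen only after the result was seen; the others were planned. SKI stayed lower in all 19 alternatives, at log2 fold changes from -0.91 to -0.46, and passed in 13, with adjusted p from 0.00241 to 0.164. It lost its call with library totals (log2 -0.69), neighbour centring (-0.46) and the GC trend removed (-0.62), and leaving out single libraries gave -0.91 to -0.61; the cause was not tested. The 1932 calls became 753 (447 higher, 306 lower) at an adjusted p under 0.01 and 1010 (626 and 384) at 2-fold or more, through the stricter threshold. Without a filter 1630 genes were higher, with 30025 genes tested in place of 16340. Centring on neighbours gave 1273 calls, 470 of them lower, and centring on chromosomes 506 lower, because both remove shifts shared by neighbouring genes. Leaving out 1 library at a time gave 740 to 2488 calls, 440 to 1410 higher and 300 to 1078 lower. Fitting fewer samples may lower such counts, but they rose to 2488 without knockout replicate 2 and 2253 without knockout replicate 3. The cause of that rise was not tested. Across the fits without 1 library, 69 to 110 of the 115 named genes kept their call and direction. Of the named genes, 58 kept theirs in every alternative in which they were tested. A gene that an alternative did not test was not counted as lost there. The 11 lists became 0 with an estimated correlation and 5 with fry, and 9 to 12 when single libraries were left out. The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated across genes at -0.17, 0.42 and -0.09, and only number 2 correlated best with its own. The highest correlation, 0.54, was between control replicate 1 and knockout replicate 3, and a block for such other pairings was not fitted. Adding the number as a block gave 2107 calls, 1103 higher and 1004 lower, with SKI at -0.74, 110 named genes and 10 lists, the apoptosis list having an adjusted p of 0.0689. Scaling moved the median log2 fold change of all genes by less than 0.1, and no named gene or list past the threshold changed direction in any alternative. Low counts limit genes near 1 CPM. In simulation 3 libraries per group recovered 78% of 2-fold changes, all in genes with an average log2 CPM above 2. Recovery at lower levels was not measured.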

Other observations

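All tests of gene families, copy number, neutrophil transcripts and a second line were chosen only after the result was seen; those of GC content, chromosome centring and gene length were added after seeing the data but before their own results were computed, and other splits were counted without a choice. Among 158 families of genes grouped by the letters their symbols open with (at least 10 tested members), 4 passed camera with the preset correlation and none with an estimated one (adjusted p = 0.998). Annexin genes (ANXA), which encode calcium-dependent membrane-binding proteins, were higher, with 4 of 10 rising and a median of 0.36 (adjusted p = 0.00629, and 0.00436 after chromosome centring). ANXA3 rose from 3.83 ± 0.649 to 21.1 ± 0.827 CPM (SD, n = 3, edgeR adjusted p = 5.39e-05). Zinc finger genes (ZNF) were lower at a median of -0.23 (adjusted p = 0.0117), with 158 of 373 on chromosome 19, and after chromosome centring their median was -0.02 (adjusted p = 0.807). Gamma protocadherin genes (PCDHGA) had a median of -0.95 (adjusted p = 0.00359, and 0.000184 after chromosome centring), but 0 of 12 passed singly in edgeR and they share exons. Keratin genes (KRT) were higher at a median of 0.55 (adjusted p = 0.0150, and 0.0201 after chromosome centring), with 3 of 11 rising, among them KRT81 and KRT86, whose values shared reads leave uncertain. After chromosome centring 4 families passed camera with the preset correlation. Among these, genes with symbols opening with RAB (adjusted p = 0.104 before and 0.0201 after) took the place of zinc finger genes.

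Chromosome 19 genes were lower and chromosome 6 genes higher in the knockout. After removal of each library's GC trend the medians were still -0.37 (SE 0.016) and 0.41 (SE 0.018), beyond the bounds of -0.2 and 0.2, which argues against GC content as the whole cause. These SEs come from resampling genes and leave out the spread between libraries. Before that removal, the medians of the knockout libraries had an SD of 0.093 for chromosome 19 and 0.017 for chromosome 6. A different copy number of these chromosomes in the 2 lines is a candidate explanation: the median passed the bound in 10 of 10 gene-order bins of chromosome 19 and in 10 of 10 of chromosome 6. No DNA was analysed here, and the bins were seen before that test was written. Whether such a difference goes with SKI loss or with the line cannot be told apart, since there was 1 line per group.

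Of 20 tested mature neutrophil genes 12 rose in the knockout and 1 fell. All 13 called members kept their call and direction after chromosome centring, and 13 of 13 after the gene length trend was removed. The median log2 fold change of the 13 was 2.25, with 2.25 after centring and 2.20 after the length trend was removed. Chromosome medians lay only between -0.48 and 0.43, so centring could hardly have ended calls of this size. It shows only that chromosome shifts were too small to make up these changes. Removal of the length trend likewise moved the median little, and shows only that this trend was too small to make up these changes. Mature neutrophils in the knockout cultures would bring S100A8 and S100A9, yet the highest level in a knockout library was 0.0572 CPM for S100A8 and 0.578 CPM for S100A9. A partial change of the myeloid programme that goes with SKI loss may account for the pattern, as may a difference between the lines that predates targeting, which the design left untested.

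Of 12 MHC class I genes 5 rose in the knockout, and only 1 of the 5 kept its call after chromosome centring. The median log2 fold change of the 5 went from 1.02 to 0.62, so calls ended because the shift of chromosome 6 was taken away while the spread stayed. The chromosome-wide shift may therefore account for part of the change of these 5 genes, of which HLA-B stayed past the threshold at 1.20 (edgeR adjusted p = 0.0239). Over all 12 tested members the median went from 0.60 to 0.24 with centring.

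Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many edgeR calls as the real split, which was the real one with 1932. The highest of the others gave 0 calls, and up to 1220 genes at an unadjusted p under 0.05, and 10 splits are too few for a share under 0.05. Knockout replicate 3 and control replicate 1 stood apart from their groups in the same way. Their deviations from the group mean correlated at -0.44 and -0.41 with gene length across genes (Spearman), and ribosomal protein genes took 21.6% and 17.4% of their counts, against at most 15.1% in the other libraries. Without both, 1627 genes were called, and 3 of the 11 lists no longer passed camera with the preset correlation, namely primary granule (adjusted p = 0.305), apoptosis (0.104) and interferon-induced genes (0.204).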
